A study of Caenorhabditis elegans with 4 samples.

How the data were processed

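ChIP-seq for REC-8 was done on adult fem-2(b245) hermaphrodites, grown at 20 °C per the series' design text. Per the labels' protocols, frozen and ground worms were crosslinked with EGS for 20 minutes and with EGS plus formaldehyde for a further 10 minutes, sonicated, and immunoprecipitated with 5 µg of affinity-purified antibody. Single-end libraries were sequenced on Illumina instruments. The 4 samples are 2 REC-8 ChIP samples and 2 input DNA samples, grouped and numbered by their titles. BWA and the genome build ce10 are named in the submitters' processing notes, and the file headers name WormBase WS220. The aligner's version, read filters, the use of the input and the treatment of duplicates or of reads with several matches are not given in the sources used here. Since reads in repeated sequence can be kept, split or dropped, these choices can make or remove peaks there.

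Peaks in the 2 replicate lists were called by a program named MACS per the file headers and source column, 1 list per ChIP sample. The series-wide list names MACS v2 as its source. How the replicates were combined for it is not stated. Each peak has a start, an end and a score as deposited by the authors, with no counts of reads. The meaning of the score is not stated in the files. Replicate scores start at 50.0 and series-wide scores at 1.31, so scores were compared by rank or ratio within a list and never in size between the replicate lists and the series-wide list. Pearson's r between the scores of the replicate lists does use their size. Different callers or settings alone can change the width and number of peaks between the lists. Peak lists give no read totals, so the depth and the precision it would give are unknown.

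From these lists the following was computed with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and, for the plots, matplotlib 3.10.9. Mitochondrial peaks were left out of all comparisons. No genome of the files' build was used, so each chromosome's extent was taken as the last base of any deposited peak on it (100.3 Mb over the 6 nuclear chromosomes), and peaks were placed by their midpoints. Peaks overlapped when they shared at least 1 bp. The overlap was tested against 100000 circular shifts of 1 list within each chromosome, which keep widths, numbers and grouping of peaks. Scores were correlated over peaks that overlap one to one. X and autosomes were compared over 100 windows of about 1 Mb by permuting windows. Central and flanking sections were compared by an exact sign-flip test over the 6 chromosomes. Distances between neighbours were compared with uniform random placement. All tests of the report are two-sided, with a threshold of 0.05 and Benjamini-Hochberg adjustment over the 5 planned tests, and separately over 4 tests of the report that were added after the values were seen. Correlations within single chromosomes, results under alternatives and the further tests of the closing section were not adjusted. The rotation tests along chromosomes in the closing section are one-sided, since they count values as high as the observed one. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. The overlap, window, sign-flip and distance procedures were tested on simulated lists. In a separate check on a sample of peaks, overlap calls equalled those of a direct search under each of the 3 overlap rules. A doubled density on X was measured as 1.97-fold, and unrelated lists gave p under 0.05 in 1 of 40 simulations.

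The peaks named, the 5 planned tests and the alternatives were fixed before the data were examined, except where stated. The named peaks are the 10 highest scoring series-wide peaks that overlap both replicates and the highest scoring peak of each chromosome. The alternatives tried were a reciprocal overlap of 50%, midpoints within 500 bp, only peaks at or above the median score, lists of equal length, covered bases, merging of peaks under 1 kb apart, other section limits, other windows, whole chromosomes as units, and each replicate list alone. Planned comparisons with genes, gene groups and base composition were not run, since the gene table at hand was of another assembly (WBcel235) and coordinates of different builds were not mixed.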

Results

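The series mapped where REC-8 sits in the genome of adult Caenorhabditis elegans hermaphrodites. REC-8 is a meiotic kleisin, a subunit of cohesin, the ring complex that holds sister chromatids together. The worms carried fem-2(b245). FEM-2 is a protein phosphatase needed for male sexual fate, so that loss of its function feminises the germline. Whether the germline of these worms, grown at 20 °C, was feminised was not analysed here. Chromatin of whole worms with a germline was immunoprecipitated with a rabbit polyclonal antibody raised against REC-8 and sequenced (ChIP-seq). The labels give 2 ChIP samples (replicates 1 and 2) and 2 samples of input DNA. The values analysed are 3 deposited peak lists, 1 for each ChIP replicate and 1 named for the series as a whole. The input samples enter only as far as the authors' peak calling used them, which is not stated. Read totals are unknown from the peak lists, so the depth behind a peak is unknown too, and a peak missing from a list cannot be read as absence of REC-8.

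The replicate 1 list held 2001 peaks, the replicate 2 list 5347 and the series-wide list 7834. Of the series-wide peaks 7831 lay on the 6 nuclear chromosomes and 3 on mitochondrial DNA. Nuclear peaks covered 1.18% of the genome in replicate 1 (median width 416 bp), 3.22% in replicate 2 (499 bp) and 2.99% in the series-wide list (293 bp). Nuclear peaks wider than 2 kb were few, with 70 in replicate 1, 72 in replicate 2 and 56 in the series-wide list. REC-8 was thus called mostly at short sites, on all 5 autosomes and X. Part of them lay near another, since merging series-wide peaks under 1 kb apart left 5859 of 7831.

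The first comparison asked whether both replicates marked the same sites. Of the 2001 replicate 1 peaks, 1573 shared at least 1 bp with a replicate 2 peak (78.6%, exact 95% interval 76.7 to 80.4). Circular shifts of the replicate 1 peaks along their chromosomes gave 6.27% on average with an upper 95% limit of 7.45%, so the observed share was 12.5 times the shifted mean (two-sided permutation test, p = 2e-05, the smallest that 100000 shifts can give; adjusted p = 3.33e-05 over the 5 planned tests). Chromosome I had the highest share, 84.0% (79.7 to 87.7), and X had 82.4% (78.2 to 86.1). Chromosomes IV and V had 73.6% (68.7 to 78.1) and 73.1% (67.4 to 78.2). In the other direction 1496 of 5347 replicate 2 peaks met a replicate 1 peak (28.0%, 26.8 to 29.2), against 2.35% after shifting. With the best scoring 2001 replicate 2 peaks only, 64.2% of replicate 1 peaks were shared, against 3.00% after shifting. All these intervals cover counting error only, and they treat peaks as independent.

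Sharing rose with score, steeply in replicate 2 and unevenly in replicate 1. Among replicate 2 peaks, 4.30% (2.74 to 6.38) of the lowest score decile and 92.9% (90.4 to 94.9) of the highest decile met a replicate 1 peak. For replicate 1 peaks the same deciles gave 65.7% (58.7 to 72.2) and 88.0% (82.7 to 92.2). Scores are the authors' peak caller's own values. They were used for ranking within a list, except in Pearson's r below, which uses their size in both replicates. At the 1383 sites where 1 peak of each replicate overlapped only the other, the scores of the replicates were correlated across peaks (Spearman's rho = 0.53, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 3.33e-05; Pearson's r = 0.73, permutation p = 1e-05). Peaks are not independent replicates, and many of the strongest shared a score of exactly 3100, namely 34 peaks in replicate 1, where 2 scored higher, and 41 in replicate 2, where 1 did.

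**Figure D1:**
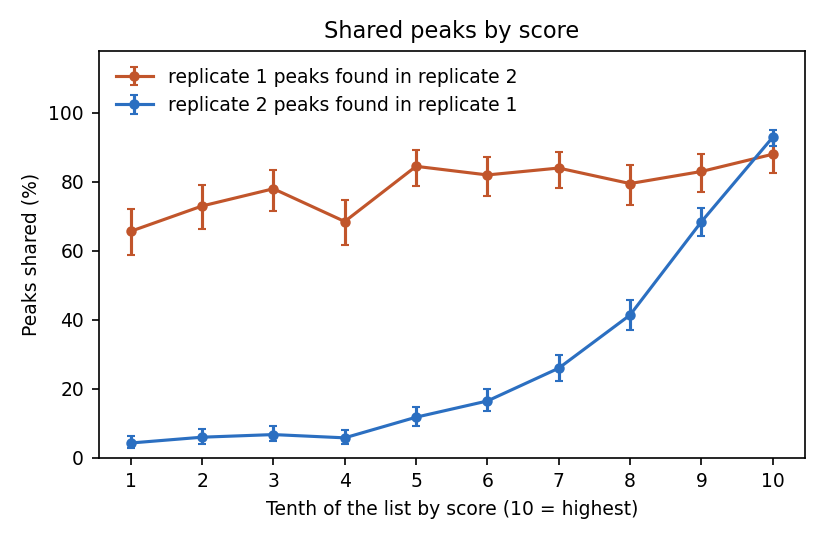
Share of peaks (%) that overlap a peak of the other replicate by at least 1 bp, by decile of the authors' score within each list, with exact 95% binomial intervals as bars. Replicate 2 peaks climb from 4.30% to 92.9%, while replicate 1 peaks run from 65.7% to 88.0%.

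The series-wide list was next set against the replicate lists. It took up most of each, since 91.5% of replicate 1 peaks (90.1 to 92.6) and 94.7% of replicate 2 peaks (94.1 to 95.3) overlapped a series-wide peak. Seen from the series-wide list, 1493 of 7831 nuclear peaks (19.1%, 18.2 to 20.0) met peaks of both replicates, 3862 (49.3%) met replicate 2 alone, 369 (4.71%) met replicate 1 alone and 2107 (26.9%) met neither. Sites found in both replicates were the strong ones, with a median series-wide score of 38.0 and a median width of 545 bp. Those found in neither had a median score of 4.37 and a median width of 196 bp. Of the highest decile of series-wide peaks by score, 93.6% met both replicates and 6.38% met replicate 2 alone. How the series-wide list combines the replicates is not stated. If its scores draw on the reads of both, sites called in both would score high partly by construction. No test was made here.

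The second comparison was between X and the autosomes. In the series-wide list X carried 99.4 peaks per Mb, close to chromosome III with 98.2 and chromosome I with 90.4. Chromosomes II and IV carried 70.0 and 68.6, and chromosome V, the longest, carried the fewest with 51.8. X thus held 22.5% of the nuclear peaks (21.6 to 23.4) on 17.7% of the nuclear length. Over windows of about 1 Mb, X averaged 99.4 ± 16.3 peaks per Mb (SD, n = 18 windows) and the autosomes 73.6 ± 25.2 (SD, n = 82 windows), a ratio of 1.35 (two-sided permutation test over windows, p = 0.00012; adjusted p = 0.00015 over the 5 planned tests). The replicates differed here. X carried 70.0 ± 13.4 peaks per Mb in replicate 2 against 49.8 ± 19.9 on the autosomes (ratio 1.41, permutation p = 9e-05). In replicate 1 it carried 21.5 ± 6.46 against 19.6 ± 7.66 (ratio 1.10, permutation p = 0.337), below chromosome III with 25.7 and chromosome I with 22.8. A test of the difference between the replicates' ratios, added after the values were seen, gave a permutation p of 0.00478 (adjusted p = 0.00637 over 4 added tests). Among the series-wide peaks seen in both replicates the ratio was 1.12 (permutation p = 0.277). The p-values measure the spread between windows of these lists and treat windows of the same chromosome as independent, although density differed between chromosomes. With whole chromosomes as units the ratio was 1.31 (exact test over whole chromosomes, p = 0.333). By that measure chromosome V lay farther from the others than X did, so X was not singled out. The same limit holds for the window tests of X that follow. The labels do not say whether the replicates came from separate cultures.

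**Figure D2:**
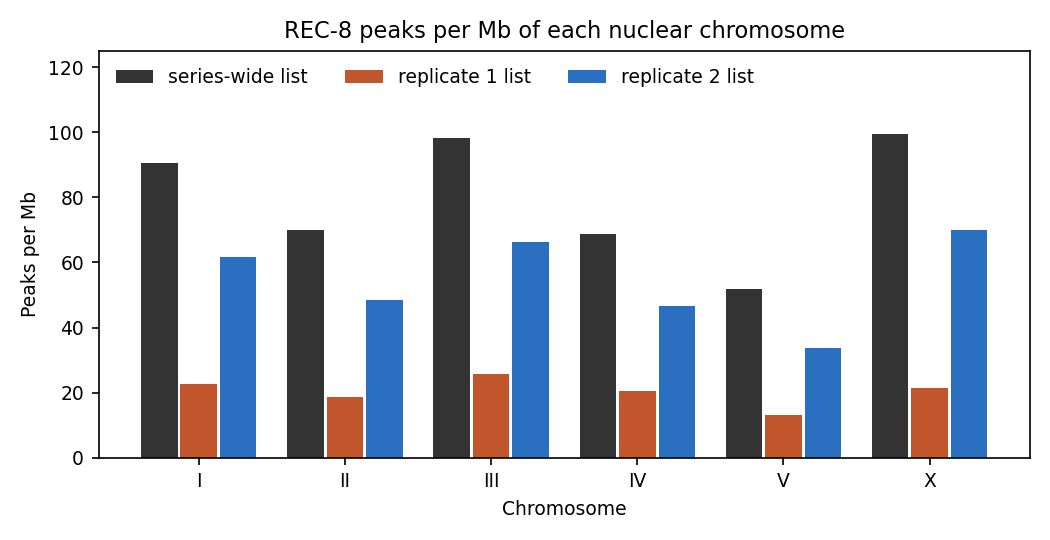
Peaks per Mb (vertical axis) on each nuclear chromosome in the series-wide list and the lists of replicates 1 and 2; each bar is 1 list on 1 chromosome, with the extent of the chromosome taken from the last deposited peak. Chromosome V is lowest in all 3 lists (51.8, 13.1 and 33.8 peaks per Mb), and X is highest in the series-wide and replicate 2 lists but not in replicate 1.

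X also held the strongest sites. Of the 10 highest scoring series-wide peaks found in both replicates, 8 lay on X. In WS220 coordinates the first was at X from 805603 to 807767 (2165 bp, score 204). The next were at X from 13513558 to 13515108 (score 201), from 1388322 to 1390979 (199), from 1888231 to 1889035 (193), from 2363800 to 2366290 (192), from 7180896 to 7182393 (191), from 1625994 to 1628309 (189) and from 16055166 to 16057950 (186). All 8 had a score of 3100 in replicate 2, and 7 of them had it in replicate 1 as well, the exception being the site at 1888231, with a replicate 1 score of 3034. The remaining 2 of the 10 were narrower sites on chromosome IV, from 3313173 to 3313880 (708 bp, score 183) and from 4727726 to 4728322 (597 bp, score 183). The highest scoring site of chromosome III ran from 1618729 to 1619504 (776 bp, score 180). Those of the other autosomes lay on II from 4047653 to 4048303 (172), on I from 3037775 to 3038432 (164) and on V from 14038324 to 14039065 (156), and each of them overlapped 1 peak in each replicate. Gene annotation of this build was not used here, so the sites are given by position.

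A count over the 100 highest scoring peaks was added after these values were seen. X held 46 of them (46.0%, 36.0 to 56.3), chromosome IV 17, chromosome I 12, chromosome II 11, chromosome III 8 and chromosome V 6. X held 2.60 of these peaks per Mb against 0.651 on the autosomes (two-sided permutation test over windows, p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 2e-05 over the 4 added tests). The replicate lists gave the same direction, with 39 of the top 100 on X in replicate 1 (permutation p = 0.00023) and 56 in replicate 2 (permutation p = 1e-05). The excess narrowed quickly below the top. X held 30 of the top 50 peaks, but 116 of the top 500 (23.2%), close to its 22.5% of all peaks; per Mb, X still exceeded the autosomes there (6.55 against 4.65, permutation p = 0.013). By score decile of the series-wide list X held 24.9% (21.9 to 28.1) of the lowest and 22.5% (19.6 to 25.6) of the highest decile. In the replicate lists the X share was highest in the highest decile, 29.5% (23.3 to 36.3) in replicate 1 and 30.3% (26.4 to 34.4) in replicate 2, with intervals that overlapped those of some other deciles and lay above those of the rest, and the difference between deciles was not tested.

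**Figure D3:**
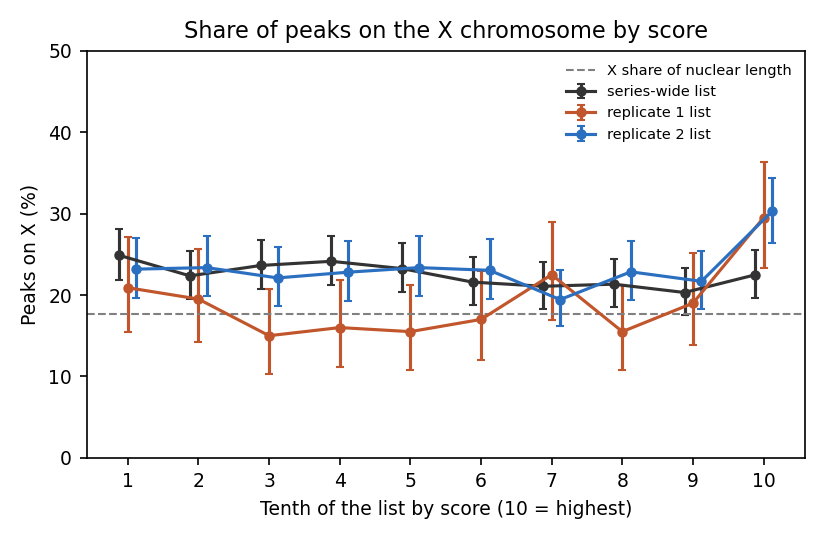
Share of peaks on X (%) by decile of the authors' score in each of the 3 lists, with exact 95% binomial intervals; the dashed line is the share of nuclear length on X, 17.7%. The highest decile reaches 29.5% in replicate 1 and 30.3% in replicate 2, and stays at 22.5% in the series-wide list.

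A further planned comparison set the central section of each chromosome, with low recombination on the autosomes, against its flanking sections, each section being 33.3% of the extent. In the series-wide list the 5 autosomes carried more peaks in the centre. Chromosome III had 112 peaks per Mb in the centre against 79.7 on its left and 103 on its right. Chromosome II had 84.5 against 45.8 and 79.8, and chromosome V had 62.5 against 46.9 and 46.0. X went the other way, with fewer in the centre than on its left (96.5) and right (107), a log2 ratio of -0.10. The mean log2 ratio of centre to flanks was 0.26 ± 0.19 (SD, n = 6 chromosomes), which did not pass the test (exact sign-flip test, two-sided, p = 0.0625; adjusted p = 0.0625; the smallest p this design allows is 0.0312). The replicates pointed in opposite directions. The ratio was 0.41 ± 0.24 in replicate 2, positive on the 5 autosomes, and -0.20 ± 0.15 in replicate 1, negative on all chromosomes but I, where it was 0.01 (exact sign-flip p = 0.0625 for each). The replicate 2 ratio was above the replicate 1 ratio on 6 of 6 chromosomes, by 0.60 ± 0.22 (SD, n = 6; exact sign-flip test added after the values were seen, p = 0.0312; adjusted p = 0.0312 over the 4 added tests). With both lists at 2001 peaks the difference was 0.51 ± 0.25 (exact p = 0.0312). With 6 of 6 chromosomes on the same side, the sign-flip test can give no other p. Each replicate list is 1 sample, so these p-values measure agreement over chromosomes and not the spread between samples. Series-wide peaks found in both replicates had a ratio of -0.03 ± 0.20 (exact p = 0.688).

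**Figure D4:**
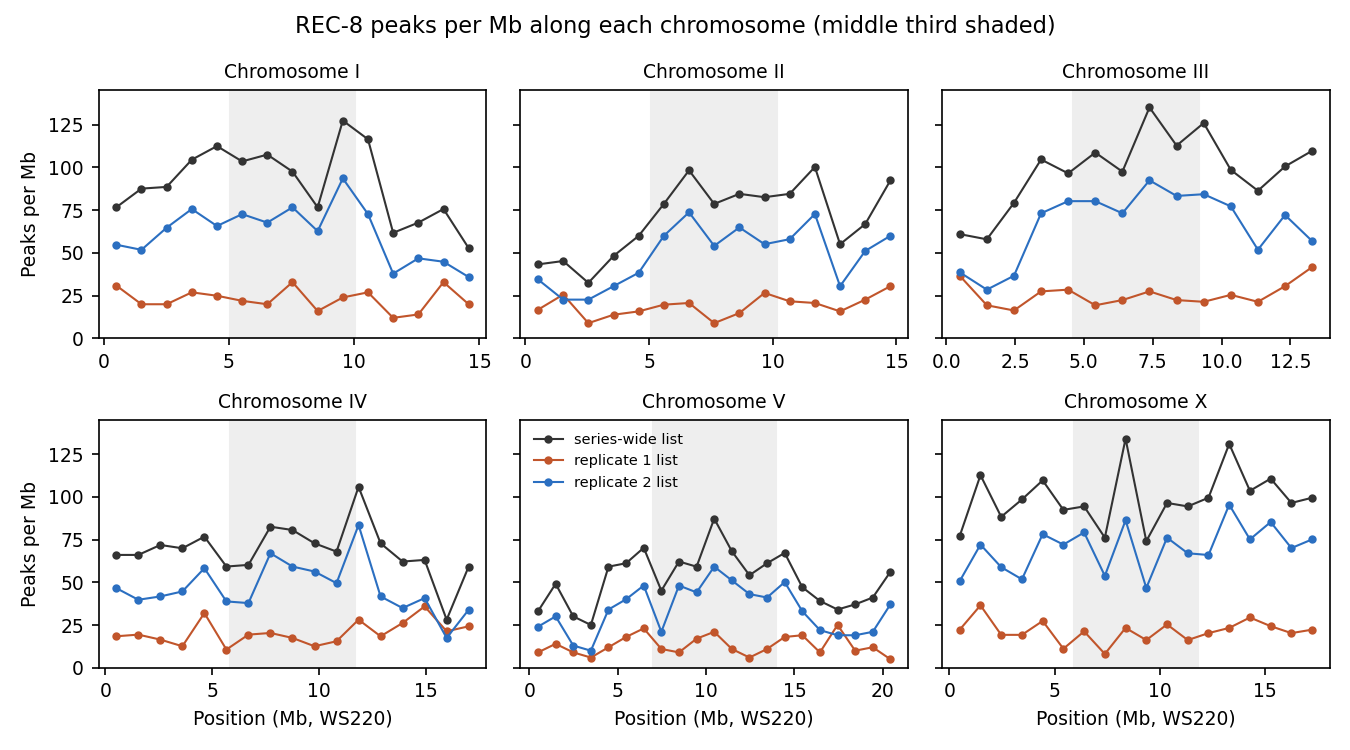
Peaks per Mb (vertical axis) in windows of about 1 Mb along each nuclear chromosome (horizontal axis, Mb in WS220) for the series-wide list and both replicate lists; the central section is shaded. The densest window lies on chromosome III with 135 series-wide peaks per Mb, and the sparsest on the left part of chromosome V with 25.1.

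Neighbouring peaks lay closer together than under uniform placement. The median distance between the midpoints of neighbouring series-wide peaks was 4875 bp, against 8554 bp for the same number of peaks placed uniformly at random on each chromosome (95% range 8356 to 8752 bp; two-sided permutation test, p = 2e-05, the smallest that 100000 draws can give; adjusted p = 3.33e-05). The ratio of the observed to the random distance was 0.57 in the series-wide list, 0.64 in replicate 2 and 0.74 in replicate 1 (permutation p = 2e-05 in each). Uniform placement ignores the differences in density along chromosomes given below, which alone shorten the median distance. Peaks under 1 kb apart were not merged for it either, although merging left 5859 of the 7831 peaks. Local grouping of sites was thus not tested apart from these. Over the 100 windows of about 1 Mb, peak densities of the replicates were correlated (Pearson's r = 0.47 and Spearman's rho = 0.53, both with a permutation p of 1e-05; adjusted p = 2e-05 for Pearson's r over the 4 added tests; r = 0.48 without the 2 windows farthest from the replicate 1 median). Windows are not independent replicates. Within single chromosomes r was 0.44 on X (permutation p = 0.0646), 0.36 on I (p = 0.189), 0.33 on V (p = 0.14) and II (p = 0.235), 0.12 on IV (p = 0.652) and 0.00 on III (p = 0.991), so within chromosomes none passed the threshold by Pearson's r; by Spearman's rho X did (0.62, p = 0.00691, unadjusted). The densest windows in the series-wide list were on chromosome III from 6891777 to 7876316 (135 peaks per Mb), on X from 7874991 to 8859364 (134) and on X from 12796860 to 13781233 (131). The sparsest were on chromosome V from 2989143 to 3985523 (25.1), on chromosome IV from 15435565 to 16464601 (28.2) and on chromosome V from 1992763 to 2989142 (30.1).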

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

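The mitochondrial genome was outside all comparisons. The series-wide list holds 3 peaks there, with scores from 7.73 to 8.76 against a nuclear median of 8.51. The result is given because it is a signal in DNA outside the comparisons. The peaks cover 97.4% of an extent of 13304 bp. That extent is the last base of these same peaks, so any sequence beyond it is left out. The share of the whole mitochondrial genome was therefore not analysed here. This choice does not set the coverage before that base: with extents taken from peaks too, nuclear series-wide peaks covered 2.99%. The replicate lists hold 0 mitochondrial peaks each. The input samples were not used here as a control for it, and no explanation was tested.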

How the results depend on the processing

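The lower-scoring peaks for X, the excess of top peaks on X, the differences between replicates and the window correlation were chosen after the data were seen. The overlap of the replicates (28.0% to 78.7% over 6 alternatives), the rank agreement of scores and the spacing of peaks kept their direction and their side of the threshold under each alternative tried. The mean log2 ratio of centre to flanks reversed with 1 replicate: it was 0.41 without replicate 1 and -0.20 without replicate 2, and it was -0.028 for peaks overlapping both replicates; the other 6 alternatives gave positive values. The X to autosome ratio was 1.41 without replicate 1 and 1.10 without replicate 2, 1.12 for peaks overlapping both replicates and 1.31 with whole chromosomes as units. The last 3 no longer passed the threshold. Whole chromosomes cannot give an exact p below 0.167 by construction. The value there was 0.333 (exact test over whole chromosomes), above that floor, since chromosome V lay farther from the others than X did. For the other alternatives that did not pass, the cause was not tested. Peaks below the median score gave 1.44. The make-up of the series-wide list moved. With a reciprocal overlap of 50%, 13.9% of its peaks met both replicates, 40.6% replicate 2 alone, 3.13% replicate 1 alone and 42.4% neither. With peaks at or above each list's median score, 46.8% met replicate 2 alone, 1.92% replicate 1 alone and 31.8% neither. The excess of top peaks on X (5 alternatives), both differences between replicates (equal list lengths) and the window correlation (2 windows left out) stayed past the threshold. Planned comparisons with genes, gene lists and base composition were not run, for want of an annotation and genome of the peaks' build. No paired analysis was possible because no values of the input samples enter a test. Unknown depth limits every statement on missing peaks, above all for replicate 1, whose list is the shortest.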

Other observations

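The widest series-wide peak, named here after its values were seen, was at the right end of chromosome I, from 15060409 to 15071199 (10791 bp). This end carries the array of ribosomal RNA genes, but whether the peak lies in it was not analysed here. The peak's score was 6.39, below the median of 8.51. Replicate 1 had a peak of nearly the same limits there, from 15060207 to 15071355, with a score of 3062 and rank 37 of 2001, and replicate 2 had none. A region on chromosome III from 324736 to 329335 (4600 bp, series-wide score 8.79) likewise overlapped 8 replicate 1 peaks and 0 replicate 2 peaks. The second widest peak, on X from 16929237 to 16939926 (10690 bp, score 107), overlapped 4 replicate 1 and 3 replicate 2 peaks. The wide sites on chromosome I from 7078985 to 7085303 (6319 bp, score 50.8) and on chromosome V from 9339800 to 9344824 (5025 bp, score 73.3) were also found in both replicates.

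The longest stretch with no series-wide peak lay on the left part of chromosome V, from 2732873 to 3204506 (472 kb). It held 1 peak of the replicate lists. On the other chromosomes the longest such stretches were 177 kb on IV, 165 kb on I, 161 kb on III, 153 kb on II and 130 kb on X.

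The 3 patterns weighed here were noticed in the data first. The tests with 100 width classes, with the replicate counts, with scores at equal peak density, with scaled autosome scores, with the replicate 2 list of equal length and along X were chosen only after results were seen.

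X holds an excess of the highest scoring peaks, 46 of the top 100. Width does not account for it, because peaks drawn from the same 10 width classes put 23.9 on X (95% range 16 to 32), and 100 finer classes put 28.2 there (20 to 36). It is not due to 1 replicate, since the smaller of the replicate counts was 39 of 100 (29.4 to 49.3), above the share of 19.04% that X had of all replicate 1 peaks. For the series-wide list only, 1 factor raising all of X (copy number or scaling) is argued against as the whole cause. There the X to autosome score ratio was 1.66 at the 99th percentile and 0.91 at the median. The first was 1.82 times the second (1.55 to 2.09), past the bound of 1.5 set before. Autosome scores multiplied by 1 factor and cut at 5 thresholds, from the 30th to the 70th percentile of score, gave 1.15 to 1.37, highest at the lowest threshold. The actual calling threshold lies lower and could not be tried, so the value that 1 factor would give there is unknown. At equal peak densities the ratio at 1 peak per Mb was 1.49 (1.19 to 1.74), 1.54 (1.296 to 1.78), 1.55 (1.2996 to 1.78) and 1.36 (1.09 to 1.59) times that at 5, 10, 20 and 50 peaks per Mb, with each interval above 1 but reaching past 1.5 on both sides, so a factor that adds to the pattern and scores not proportional to signal stay open. In the replicate lists no interval was computed. The score ratio was 1.16 at the 99th percentile and 1.14 at the median in replicate 1, and 1.93 and 1.02 in replicate 2. The X value at the 99th percentile was the repeated score of 3100 in both, which only 2 replicate 1 peaks and 1 replicate 2 peak exceeded. With an autosome value of 2663 in replicate 1, the ratio there had little room to rise. That it stayed within the bound therefore decides nothing. At the 90th percentile, where X lay below 3100, the ratios were 2.28 and 1.31. No biological explanation was tested, and whether these sites coincide with known X-specific elements was not analysed here.

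Replicate 1 peaks missing from replicate 2 lay more often in the flanking sections, which make up all but the central 33.3% of each extent. The share there was 79.0% of 428 (74.8 to 82.7), against 67.2% of the 1573 shared peaks (64.8 to 69.5). Weak peaks near the threshold do not account for all of it, since within 4 score classes the difference was 12.6 percentage points (3.93 to 20.8 over resampled windows), although in the highest class it was small, 76.5% against 74.2%. The longer list of replicate 2 does not account for all of it either, since against its best 2001 peaks 76.5% of 716 missing and 65.9% of 1285 shared replicate 1 peaks were in the flanking sections, a difference of 10.6 percentage points (4.16 to 16.6). Replicate 2 peaks missing from replicate 1 went the other way, with 57.9% of 3851 in the flanking sections against 67.9% of 1496 shared ones. Both directions go with the opposite centre to flank ratios of the replicates given above. Differences between the samples or their background, and reads in repeats near the ends, remain open and untested.

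Scores of replicate 1 peaks were higher in the leftmost 10% of X, the end that carries the pairing centre of this chromosome, with a median of 354 over 48 peaks against 143 over the rest of X. This section was picked after the medians of 180 sections had been seen, 10 on each chromosome in each of the 3 lists, and its ratio of 2.48 was the highest of them. Allowing for that choice, 15.3% of 10000 rotations of the scores along the chromosomes gave a highest ratio as large, so chance placement was not excluded. Without the allowance 1 of 381 rotations along X (0.262%) gave such a median, the smallest share that these rotations can give. In replicate 2 the medians were 192 over 109 peaks and 157, and 9.51% of rotations gave a value as high, so that a rise in replicate 1 alone and a rise in both replicates cannot be told apart. No biological explanation was tested.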
